A study of Danio rerio with 14 samples.

How the data were processed

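RNA was sequenced in bulk from the distal tip of fin rays of zebrafish (Danio rerio), a strip of about 250 µm per ray. There were 5 times, the first on the day of amputation, before regrowth, and the others during regrowth. Times are given as days post amputation (dpa). The labels name them 0, 3, 7, 10 and 14 dpa, and the design text gives the first regrowth time as 3.5 days. The group is called 3 dpa here, and 3.5 was used where time entered a fit as a number. Per the design text each library came from a separate pool of 10 animals, with 3 pools per time, and at 14 dpa only 2 pools gave RNA of sufficient quality, so there were 14 libraries. The p-values therefore measure the spread between pools of animals.

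The deposited values are TPM per gene, transcript abundances corrected for length and scaled to the same total in every library, as made by the authors. Trim Galore 0.6.7, cutadapt 3.5, Salmon 1.4.0 and the danRer11 genome build are named, per the submitters' processing notes. How transcripts were summed to genes, and whether genes were filtered, is not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. Salmon divides reads among near-identical genes by estimation, so values within families such as the globins, mx, mpeg1, chemokine, hsp70 and actinodin genes are uncertain. Of 14836 genes in the table, 939 were at 0 in every one of the 14 libraries. Gene symbols are those of the table, and no coordinates are given, because no reference of the build used by the submitters was used here.

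Genes with at least 1 TPM in at least 2 libraries were kept, which left 11272. Values were transformed as log2(TPM + 1) with no further scaling between libraries. Every log2 change below is on that scale, which understates the change of low genes. A linear model with 1 mean per time was fitted over the 14 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that followed mean expression (trend). Contrasts were each time against 0 dpa, consecutive times, and 14 against 3 dpa, all two-sided. A moderated F test over the 4 contrasts against 0 dpa tested change at any time. A slope per day was fitted over the 11 libraries from 3 to 14 dpa. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called past the threshold. Levels are mean TPM ± SD, and log2 changes are given ± standard error.

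Lists of 19 gene groups and 13 sets of cell type markers were fixed before the data were examined, as were the model, the alternatives below and the rule for naming genes. The gene groups were Fgf ligands, Fgf receptors, Fgf/Erk feedback, Wnt, Hedgehog, Bmp and Tgfb, retinoic acid, Notch, Yap/Taz, blastema, actinotrichia, osteoblast, osteoclast, cell cycle, matrix, fin length, positional, stress and immediate early, and interferon genes. The marker sets were for basal epidermis, superficial epidermis, fibroblasts, macrophages, neutrophils, lymphocytes, endothelium, glia and nerve, pigment cells, muscle, erythrocytes, ionocytes and the lateral line. Across these lists 17 genes stood on 2 or more. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists, and again with the correlation estimated from the data. It was also tested with fry, which asks whether the members moved one way on balance and does not compare them with other genes. Fry was run only on the values as deposited. A shift of most genes between times can thus add to its result. Members were also adjusted within their own list.

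For 3 against 0 dpa, 14 against 0 dpa and the slope, the 8 genes with the largest rise and the 8 with the largest fall past the threshold could be named, and 3 each for the other contrasts. They needed a mean of at least 5 TPM in the higher group, no overlap between the libraries of both groups and a symbol that is not a clone name. Up to 4 members past the threshold with the largest change could be named per list. Members of the Fgf ligand, Fgf receptor, Erk feedback and fin length lists could be named whether or not they passed. Some members of these lists are not analysed here.

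The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, variances without trend, library weights, the replicate number as a block, only the libraries of both groups compared, leaving out each library in turn, and day 3 or the rank of time for the slope. Leaving out 4 libraries together, which leaves 1 library at 10 dpa and 2 each at 0 and 7 dpa, repeating the list tests with 1 library left out, and a model with the first component of the spread within times as a covariate, were chosen after seeing the data. The model was tested on simulated data with 11272 genes, each drawn independently of the others. Spread shared between genes within a library was not simulated, so the false calls below do not measure its effect. For 3 against 0 dpa it called 43% of 100 genes with a true log2 change of 1 and 94% of 100 with a change of 2, with 9 false calls. For the slope it called 55% of 100 genes changing by 0.1 per day and 92% of 100 changing by 0.2, with 15 false calls. Far fewer genes were changed there than passed in the data, 6159 at 3 dpa and 3473 for the slope. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so these percentages do not give the share of real changes missed.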

Results

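Transcripts of the distal tip of fin rays were measured in 14 libraries, 3 each at 0, 3, 7 and 10 dpa and 2 at 14 dpa. The 0 dpa libraries were taken on the day of amputation, before regrowth, and served as the reference. The tissue within the strip may differ in position and maturity between times, which cannot be told apart from time. The study's title names Erk signalling gradients that decay and expand as the fin recovers its size, so transcripts of the Fgf/Erk pathway were examined beside those of skeletal and wound tissues. Of 11272 genes tested, 5364 changed at any time (limma moderated F test). Within a time, libraries correlated across genes at 0.953 to 0.991, and no libraries held identical values.

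The first principal component held 53.2% of the variance and separated 3 dpa from 0 dpa, with later times between them. The second held 20.3% and set apart 4 libraries, namely 0 dpa replicate 1, 7 dpa replicate 2 and 10 dpa replicates 2 and 3. Their scores lay between 27.2 and 47.9, and those of the other 10 between -31.0 and -0.236. The immediate early gene fosb, an AP-1 subunit induced within minutes of a stimulus, was at 1348, 1702, 886 and 1343 TPM in these 4 libraries and between 23.0 and 144 TPM in the others. A first component was also taken from the spread within times. Its scores were 0.443, 0.480, 0.147 and 0.294 in these 4 libraries, in the same order, and -0.441 to 0.136 in the others. Along it, the median loading of each list was placed among 10000 random lists of like expression. It lay at percentile 100 for stress and immediate early genes, 100 for the cell cycle, 99.8 for Erk feedback, 99.6 for interferon, 99.5 for actinotrichia, 99.5 for lymphocytes, 99.2 for macrophages and 97.7 for osteoblasts. At the other end it lay at 0.07 for Notch, 0.07 for erythrocytes, 1.11 for matrix and 1.92 for superficial epidermis.

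**Figure D1:**
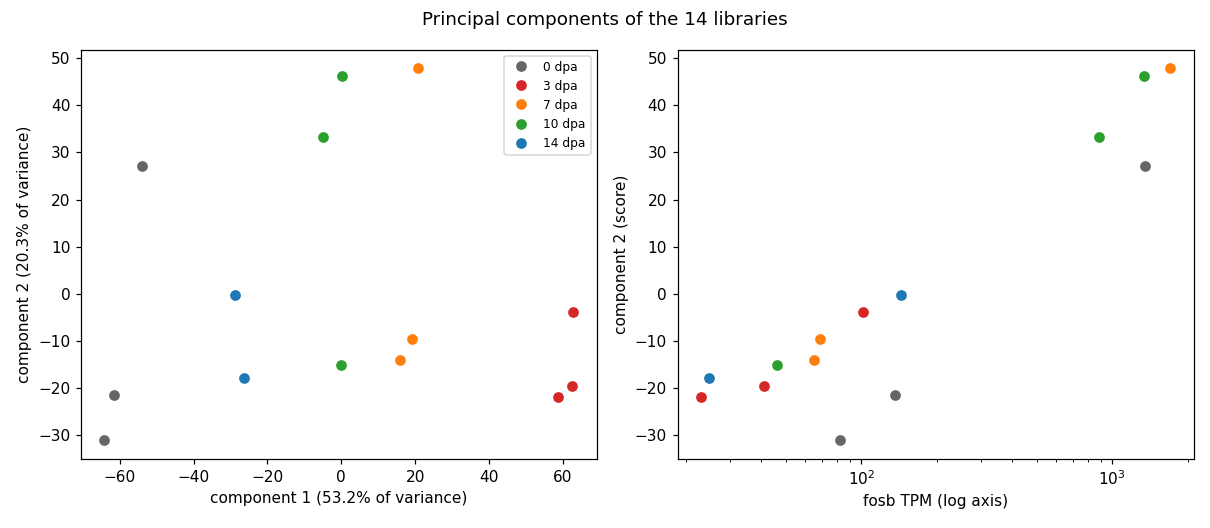
Scores of the 14 libraries on the first and second principal component of log2(TPM + 1), coloured by time (left), and the second component against fosb in TPM on a log axis (right). Each point is 1 library. The 4 libraries with the highest scores on the second component are 0 dpa replicate 1, 7 dpa replicate 2 and 10 dpa replicates 2 and 3.

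At 3 dpa, transcripts of matrix proteins were among the largest rises over 0 dpa. Transcripts of enam, which encodes the secreted matrix protein enamelin, went from 5.84 ± 2.47 to 4903 ± 542 TPM (SD, n = 3 each), a log2 change of 9.55 ± 0.26 (adjusted p = 9.42e-11). The actinodins and1 and and2, which build the unmineralised fibrils of the fin tip, rose to 14084 ± 1179 and 4967 ± 289 TPM, with log2 changes of 6.41 ± 0.31 and 7.77 ± 0.31. Further rises were in lama1, a laminin chain (6.77 ± 0.39), the calcium-binding phosphoprotein scpp7 (6.69), the globin cygb1 (6.44), versican (vcana, 6.38) and tenascin C (tnc, 6.15). Among the 8 largest falls were the perforin family gene mpeg1.3 (-6.25 ± 0.32), the lubricin gene prg4a (-5.57 ± 0.38), the chemokine genes ccl27b (-5.12) and ccl19a.2 (-4.45), and pck1 (-4.49), of gluconeogenesis. Also lower were hmgcra (-4.45), the rate-limiting enzyme of sterol synthesis, the Hsp70 family gene hspa12a.3 (-5.08) and irg1l (-4.62), a relative of the itaconate-producing enzyme.

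In all, 6159 genes passed the threshold at 3 dpa, 3945 higher and 2214 lower. The median gene was 0.24 higher at 3 dpa on the log2 scale, 0.19 at 7, 0.16 at 10 and 0.30 at 14 dpa, and these shifts should be set against the changes given here. With median-of-ratios scaling they were 0.02, -0.02, -0.04 and 0.03, and at 3 dpa 2933 genes were higher and 3009 lower. The share of higher genes among those past the threshold was thus 64.1% as deposited and 49.4% after scaling.

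Blastema genes rose at 3 dpa, 22 of 28 tested, and the other 6 did not pass (camera adjusted p = 9.01e-09, and adjusted p = 0.0102 with an estimated correlation). They included the leptin gene lepb (6.15 ± 0.53), tph1b of serotonin synthesis (5.86 ± 0.22) and the homeobox gene msx2b (4.56 ± 0.37). Actinotrichia genes rose in 11 of 11 cases (adjusted p = 1.71e-06, and adjusted p = 0.175 with an estimated correlation). Of 21 osteoblast genes, 17 rose and 1 fell (adjusted p = 2.52e-07, and adjusted p = 0.140 with an estimated correlation). Without the 4 libraries that stand apart 18 rose and 1 fell. Collagen X (col10a1a) gained 5.93 ± 0.16, collagen I (col1a1a) 5.19 ± 0.21, the bone protein gene ifitm5 5.15 ± 0.35 and phospho1, a phosphatase that starts mineralisation, 4.26 ± 0.32. Of 22 matrix genes 19 rose (adjusted p = 1.65e-07, and adjusted p = 0.0628 with an estimated correlation), among them serpinh1b, a collagen chaperone (5.43), and the metalloprotease adam8a (4.97). Fibroblast markers rose in 9 of 11 and fell in 1 (adjusted p = 0.000752, and adjusted p = 0.140 with an estimated correlation), led by decorin (dcn, 4.15) and twist1a (3.19). Of 39 cell cycle genes 27 rose (adjusted p = 4.02e-05, and adjusted p = 0.427 with an estimated correlation), including the cyclins ccne1 (2.16) and ccnb1 (1.82). Without the 4 libraries, 37 cell cycle genes passed.

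Among 12 Fgf ligands, 7 rose and 1 fell at 3 dpa, and the list as a whole did not pass in camera (adjusted p = 0.0706) but did in fry, pointing up (2.18e-07). The largest rise was in fgf20a, which is needed to start fin regeneration, from 1.89 ± 0.704 to 27.3 ± 5.83 TPM (SD, n = 3 each, log2 change 3.30 ± 0.27, adjusted p = 7.97e-07). The ligand genes fgf3 (2.84 ± 0.19), fgf2 (1.91 ± 0.39), fgf4 (1.57 ± 0.22) and fgf10a (1.27 ± 0.31) also rose, and fgf18a fell (-0.90 ± 0.22). Of 7 receptor genes 4 rose (camera adjusted p = 0.139, fry 0.00156, up), the most in the decoy-like receptors fgfrl1b (2.02) and fgfrl1a (1.98).

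Transcriptional targets and regulators of Erk moved both ways at 3 dpa. The list members dusp6, egr1 and spred2a were absent under these symbols from the deposited values and could not be tested. Of 20 tested, 7 rose and 6 fell (adjusted p = 0.834), with a median of -0.04, a mean of 0.10 and a camera test that pointed down, while fry pointed up (adjusted p = 0.0311). The list lay at percentile 99.8 on the first component within times. Without the 4 libraries that stand apart 9 rose and 6 fell, with camera pointing up (adjusted p = 0.988). The Ets factors induced by Fgf and Erk rose, namely etv5b (2.34 ± 0.22, adjusted p = 2.14e-06), etv5a (1.59 ± 0.19) and etv4 (1.33 ± 0.22). So did myca, a Myc gene (2.88 ± 0.18), and spry1, a Sprouty antagonist of the pathway (1.92 ± 0.28), while spry4 gave 0.56 ± 0.34 (adjusted p = 0.180). The Erk phosphatase gene dusp7 fell (-1.04 ± 0.08, adjusted p = 6.79e-07). The AP-1 gene fosl1a also fell (-2.18 ± 0.75, adjusted p = 0.0263), but at 0 dpa it was at 392 TPM in replicate 1 and 143 and 94.3 in the others. Without 0 dpa replicate 1 its change was -1.60 (adjusted p = 0.103). Leaving out 3 dpa replicate 2 or 3 gave adjusted p = 0.0601 and 0.0770.

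Of 13 genes tied to fin length, 5 rose and 4 fell (adjusted p = 0.556). The hyaluronan link protein gene hapln1a (3.71 ± 0.15), the guidance gene sema3d (3.06 ± 0.22), the calcineurin regulator rcan2 (2.31) and scube3 (2.06), a secreted signalling cofactor, rose. The potassium channel gene kcnk5b, in which activating mutations lengthen fins, was at 27.7 ± 2.40 TPM at 0 dpa and 18.9 ± 2.53 at 3 dpa (log2 change -0.54 ± 0.17, adjusted p = 0.0178). This call was lost without 0 dpa replicate 2 (-0.48, adjusted p = 0.0635) or 3 dpa replicate 3 (-0.43, adjusted p = 0.0711).

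The Wnt, Hedgehog, Bmp and Tgfb and positional lists were called higher at 3 dpa. Wnt pathway genes rose in 19 of 25 and fell in 2 (adjusted p = 0.000752, and adjusted p = 0.175 with an estimated correlation), with the secreted antagonist genes sfrp2 at 4.26 ± 0.29 and dkk1a at 3.19 ± 0.44. Hedgehog genes rose in 9 of 11 (adjusted p = 0.00196, and adjusted p = 0.175 with an estimated correlation), including the ligand shha (3.36 ± 0.38) and the transcription factor gli2a (2.82). Bmp and Tgfb genes rose in 21 of 27 (adjusted p = 0.000117, and adjusted p = 0.175 with an estimated correlation), led by tgfb2 (2.99) and the activin subunit inhbab (2.88). Positional genes rose in 20 of 25 (adjusted p = 1.57e-05, and adjusted p = 0.175 with an estimated correlation), such as the patterning factor genes hoxa13a (3.04) and tbx18 (3.39). In the retinoic acid list 9 of 18 rose and 3 fell (adjusted p = 0.256), with aldh1a2, which makes retinoic acid, at 4.17 ± 0.16, and the retinol carrier rbp4 at -2.99 ± 0.40. Notch genes went both ways, 6 up and 4 down of 19 (adjusted p = 0.822, median 0.10, mean 0.25, test pointing down), with her6, a target gene, at 3.10 and the ligand dlc at -3.19. In the Yap/Taz list 1 rose, the partner factor tead1a (1.73), and 3 fell of 12, including the targets ccn2b (-2.45) and amotl2b (-1.70). That list was called lower (adjusted p = 0.0450, and adjusted p = 0.284 with an estimated correlation), and its adjusted p was 0.0581 with median-of-ratios scaling, 0.0890 without 0 dpa replicate 2 and 0.158 without 3 dpa replicate 3.

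Interferon genes fell at 3 dpa in 21 of 21 cases, as they did without the 4 libraries that stand apart (adjusted p = 8.57e-12, and adjusted p = 0.154 with an estimated correlation). The regulator irf7 changed by -2.58 ± 0.59 and mxe, of the antiviral Mx family, by -2.44 ± 0.17. Superficial epidermis markers fell in 10 of 15 and rose in 1 (adjusted p = 4.02e-05, and adjusted p = 0.175 with an estimated correlation), for example agr2 of mucus-producing cells (-2.18) and icn2, an ictacalcin (-2.13). Pigment cell markers fell in 10 of 17 (adjusted p = 1.84e-05, and adjusted p = 0.175 with an estimated correlation), including mlpha (-2.38), which tethers pigment granules, and tyr (-1.85), the first enzyme of melanin synthesis. Lymphocyte markers fell in 7 of 9 and rose in 1 (adjusted p = 0.00110, and adjusted p = 0.187 with an estimated correlation), with the T cell kinase genes lck at -2.30 and zap70 at -2.01. Macrophage markers fell in 7 of 16 and rose in 1 (adjusted p = 0.00663, and adjusted p = 0.418 with an estimated correlation), the granulin gene grn2 at -2.61. The median loading of both immune lists lay high on the first component within times. Without the 4 libraries that stand apart 8 macrophage and 7 lymphocyte markers fell.

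Vessel and blood markers were called higher at 3 dpa. Endothelium markers rose in 13 of 18 and fell in 2 (adjusted p = 0.0287, and adjusted p = 0.228 with an estimated correlation), with egfl7, secreted by vessels, at 2.62 and lyve1a, a lymphatic marker, at -4.00. Erythrocyte markers rose in 8 of 11 and fell in 1 (adjusted p = 0.0356, and adjusted p = 0.427 with an estimated correlation), the globin genes hbba1 by 2.87 and hbaa1 by 2.59. Without the 4 libraries neither list passed (adjusted p = 0.0873 and 0.147), nor did they without 0 dpa replicate 1, 1 of the 4 (0.0670 and 0.108), and erythrocytes also not without 3 dpa replicate 3 (0.0748).

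The remaining lists did not pass in camera at 3 dpa. They were osteoclasts with 3 up and 1 down of 6 (adjusted p = 0.497), neutrophils with 3 and 5 of 11 (adjusted p = 0.206), and glia and nerve with 4 and 6 of 11 (adjusted p = 0.223). Muscle had 2 of 4 up (adjusted p = 0.186) and ionocytes 2 of 8 down (adjusted p = 0.421). Stress and immediate early genes had 2 up and 6 down of 23 (adjusted p = 0.256, median 0.03, mean -0.24, test pointing down), but 6 up and 6 down without the 4 libraries (adjusted p = 0.359). Basal epidermis had 4 and 4 of 12 (adjusted p = 0.409, median -0.31, mean 0.09), and the lateral line 1 and 2 of 7 (adjusted p = 0.421, median -0.39, mean 0.13), both with a test pointing down. In fry 26 of the 32 lists passed at 3 dpa, among them the 18 called by camera. The others, all pointing up, were Fgf ligands, Fgf receptors, Erk feedback, retinoic acid (4.80e-06), Notch (0.0161), osteoclasts (0.00750), fin length (3.59e-06) and muscle (8.09e-09). The median gene was itself 0.24 higher at 3 dpa as deposited, and fry was not repeated with scaling. These upward calls may therefore reflect that shift. Adjusted over the list alone, the counts of risen and fallen genes differed for retinoic acid with 10 and 3, cell cycle with 29 and 0, matrix with 20 and 0, superficial epidermis with 1 and 11, macrophage with 1 and 6, lymphocyte with 1 and 8 and ionocyte with 0 and 0, and were the same for each of the other lists.

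**Figure D2:**
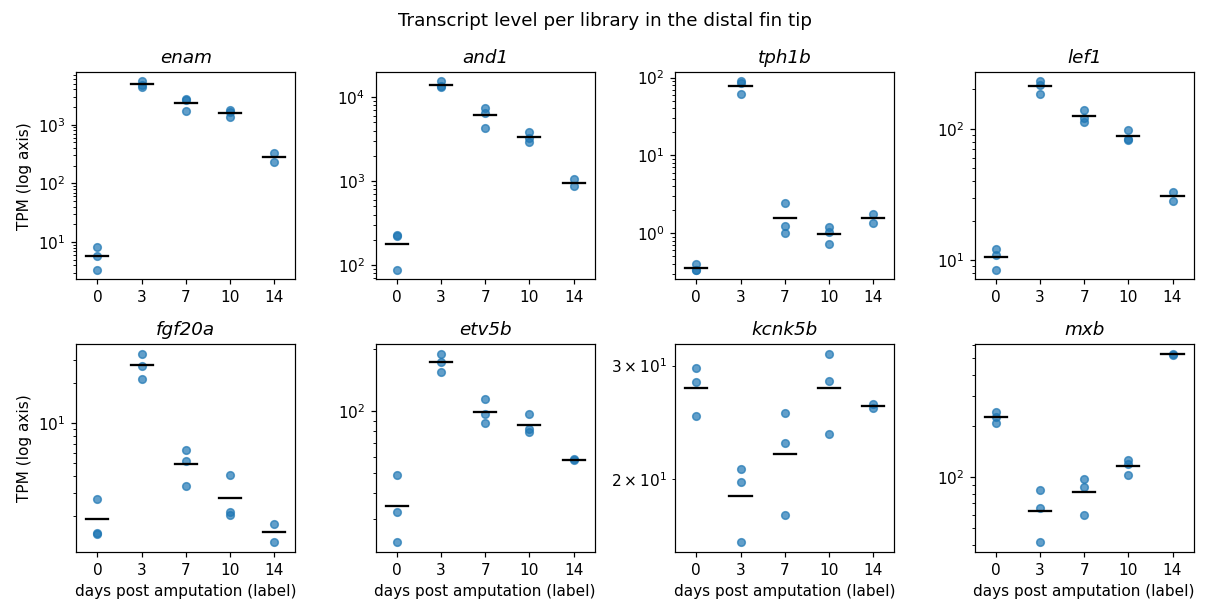
TPM per library on a log axis for 8 genes at 0, 3, 7, 10 and 14 dpa. Points are libraries and bars are means. Mean enam was 4903 TPM at 3 dpa and 281 at 14 dpa, and mean mxb 63.5 and 525.

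At 7 dpa the largest rises over 0 dpa were in enam at 8.48 ± 0.26, and2 at 6.37 ± 0.31 and col10a1a at 5.56 ± 0.16. At 10 dpa these were 7.92 ± 0.26, 5.18 ± 0.31 and 5.21 ± 0.16. The largest falls at 7 dpa were in ccl19b, a chemokine gene (-3.38 ± 0.44), pck1 (-3.19 ± 0.37) and irg1l (-3.32 ± 1.13, adjusted p = 0.0408). The irg1l call was lost without any 1 of 0 dpa replicates 1, 2 and 3 (adjusted p = 0.109, 0.0748 and 0.0643) and without 7 dpa replicates 1 or 3 (0.0648 and 0.165). At 10 dpa they were in the vitamin D hydroxylase gene cyp24a1 (-3.44 ± 0.79), pck1 (-2.64 ± 0.37) and ccl19b (-2.62 ± 0.44). The cyp24a1 change had adjusted p = 0.142 (-2.28) without the 4 libraries, where 1 library remained at 10 dpa and was assumed to vary like the other groups. Osteoblast genes rose in 19 of 21 at 7 dpa (adjusted p = 3.02e-15, and adjusted p = 0.0208 with an estimated correlation) and in 19 at 10 dpa (adjusted p = 1.49e-20, and adjusted p = 0.00919 with an estimated correlation), the same counts as adjusted over the list alone, and in 18 and 17 without the 4 libraries. Interferon genes fell in 18 of 21 at 7 dpa (adjusted p = 2.14e-14, and adjusted p = 0.0743 with an estimated correlation) and in 6 at 10 dpa (adjusted p = 9.21e-11, and adjusted p = 0.107 with an estimated correlation), 20 and 9 adjusted over the list alone. Pigment cell markers, lower at 3 dpa, were called higher at 10 dpa, 9 of 17 (adjusted p = 0.000374, and adjusted p = 0.214 with an estimated correlation), 10 adjusted over the list alone.

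Fgf ligands rose at 7 dpa in 9 of 12 (adjusted p = 0.0151, and adjusted p = 0.0743 with an estimated correlation), and at 10 dpa 2 rose and the list did not pass in camera (adjusted p = 0.103) but did in fry (5.55e-05, up). Fgf receptor genes rose in 5 of 7 at 7 dpa (adjusted p = 0.00449, and adjusted p = 0.208 with an estimated correlation) and in 5 at 10 dpa (adjusted p = 0.00100, and adjusted p = 0.157 with an estimated correlation), 7 and 6 adjusted over the list alone. Of 20 Erk feedback genes 7 rose and 1 fell at 7 dpa (adjusted p = 0.858, median -0.11, mean 0.24, test pointing up, and fry 0.0379, up), and 9 rose and 2 fell without the 4 libraries. At 10 dpa 6 of them rose and the list did not pass in camera (adjusted p = 0.465) but did in fry (0.0293, up), 7 adjusted over the list alone.

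At 7 dpa 3442 genes passed, 2420 higher and 1022 lower, and with median-of-ratios scaling 1823 higher and 1908 lower. At 10 dpa 1885 passed, 1577 higher and 308 lower, and after scaling 1212 and 857. The 10 dpa count was 1253 without 0 dpa replicate 2, 1196 without 0 dpa replicate 3 and 1217 without 10 dpa replicate 3. Of the 32 lists 17 passed at 7 dpa and 16 at 10 dpa. Without 7 dpa replicate 2, 1 of the libraries that stand apart, the cell cycle list did not pass at 7 dpa (adjusted p = 0.118). With an estimated correlation 4 did at each time, the blastema, osteoblast, matrix and fibroblast lists.

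At 14 dpa skeletal and matrix transcripts were still above 0 dpa. The level of enam was 281 ± 67.4 TPM (SD, n = 2), a log2 change of 5.41 ± 0.29 (adjusted p = 5.36e-07), and col10a1a gained 3.49 ± 0.17. The phosphoprotein gene scpp8 (3.90 ± 0.51), the fibrillar collagen genes col11a2 (3.38 ± 0.24) and col11a1b (2.93 ± 0.27), lama1 (3.29), and2 (3.19) and spon2a (2.91), which encodes a spondin of the matrix, completed the 8 largest rises. The largest falls were in mpeg1.3 (-2.73 ± 0.36), hsd3b7, a bile acid synthesis gene (-2.58 ± 0.42, adjusted p = 0.0558 without 14 dpa replicate 1), and pck1 (-2.23 ± 0.41, -1.42 and adjusted p = 0.0711 without 14 dpa replicate 2).

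Osteoblast genes rose at 14 dpa in 14 of 21 (adjusted p = 7.48e-11, and adjusted p = 0.0813 with an estimated correlation), including osteopontin (spp1, 2.62 ± 0.19), ifitm5 (2.52) and phospho1 (2.23). Blastema genes rose in 17 of 28 (adjusted p = 6.64e-07, and adjusted p = 0.0240 with an estimated correlation), with hapln1a at 2.15 ± 0.17 and tnc at 2.55 ± 0.29. Matrix genes rose in 11 of 22 (adjusted p = 7.69e-06, and adjusted p = 0.0880 with an estimated correlation), cell cycle genes in 15 of 39 (adjusted p = 0.000925, and adjusted p = 0.538 with an estimated correlation) and fibroblast markers in 7 of 11 (adjusted p = 0.00359, and adjusted p = 0.123 with an estimated correlation), led by dcn (1.57). The number of members past the threshold rested on single libraries. Without 0 dpa replicate 2 or 3 and 14 dpa replicate 1 or 2, in this order, it was 9, 11, 5 and 8 for blastema genes, 4, 3, 2 and 2 for fibroblast markers and 5, 7, 0 and 2 for cell cycle genes, of which 19 had an unadjusted p under 0.05 in limma where the count was 0. For matrix genes it was 4 and 6 without 14 dpa replicate 1 or 2. The list tests of these 5 groups passed with each library left out. These member counts are as deposited, and scaling also moved calls. With median-of-ratios scaling 269 genes in all were higher at 14 dpa, against 1143 as deposited. In limma the calls of prrx1a (adjusted p = 0.236), pdgfra (0.217), ccne1 (0.0877) and serpinh1b (0.0824) were then lost. Of the 10 lists called at 14 dpa, 9 kept their call with this scaling.

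Other lists were called at 14 dpa with less room. Actinotrichia genes (4 of 11 risen, adjusted p = 0.0131, and adjusted p = 0.537 with an estimated correlation) lost the call without the 4 libraries (adjusted p = 0.115) or 14 dpa replicate 2 (0.114, 2 risen). Positional genes (7 of 25 risen, adjusted p = 0.0131, and adjusted p = 0.454 with an estimated correlation) lost it without the 4 libraries (0.0880) or 14 dpa replicate 1 (0.0711), and 1 and 3 members rose without 14 dpa replicate 1 or 2. Neutrophil markers (4 of 11 risen, adjusted p = 0.0428, and adjusted p = 0.353 with an estimated correlation) lost it without the 4 libraries (0.123) or 0 dpa replicate 1 or 3 (0.0976 and 0.0712), and 1 member rose without 14 dpa replicate 1 or 2. Basal epidermis markers were called lower with 2 of 12 fallen (adjusted p = 0.0131, and adjusted p = 0.103 with an estimated correlation, median -0.05, mean 0.01, and fry 0.456). That call was lost with median-of-ratios scaling (adjusted p = 0.139) and without 0 dpa replicate 3 (0.0512), and 1 member fell without 0 dpa replicate 1. Without 0 dpa replicate 2 or 3 or 14 dpa replicate 1 or 2, 0 fell in limma, with 3, 2, 3 and 1 at an unadjusted p under 0.05. Lymphocyte markers were called lower (adjusted p = 0.00992, and adjusted p = 0.454 with an estimated correlation), although 0 of 9 passed in limma and 0 had an unadjusted p under 0.05, and their adjusted p was 0.0880 without the 4 libraries and 0.552 in fry.

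Fgf ligands (1 of 12 up, adjusted p = 0.415) and Erk feedback genes (2 up and 1 down of 20, adjusted p = 0.118) did not pass in camera at 14 dpa. Both camera tests pointed down and both fry tests up (adjusted p = 0.0345 and 0.433), while the medians were 0.23 and 0.10 and the means 0.17 and 0.04. The median gene was 0.30 higher at 14 dpa, above each of these, so the upward fry results may reflect that shift. Without the 4 libraries 5 Erk feedback genes rose and 1 fell. The log2 change of fgf20a from 0 dpa was -0.18 ± 0.30 (adjusted p = 0.713). Adjusted over the list alone, counts up and down differed for Erk feedback with 4 and 1, Wnt with 9 and 1, Hedgehog with 5 and 0, Bmp and Tgfb with 6 and 0, retinoic acid with 4 and 2, blastema with 21 and 0, actinotrichia with 6 and 0, osteoblast with 18 and 0, osteoclast with 4 and 0, cell cycle with 21 and 0, matrix with 16 and 0, positional with 10 and 0, interferon with 5 and 4, superficial epidermis with 5 and 2, fibroblast with 9 and 0, neutrophil with 5 and 0, pigment cell with 4 and 0, muscle with 2 and 0, erythrocyte with 4 and 0 and ionocyte with 4 and 0.

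In all 1265 genes passed at 14 dpa, 1143 higher and 122 lower, but with median-of-ratios scaling 525 passed, 269 higher and 256 lower, and after quantile normalization 409. This count rested on single libraries. It was 180 and 281 without 14 dpa replicate 1 or 2, 1984, 488 and 541 without 0 dpa replicate 1, 2 or 3, and 3448 without the 4 libraries that stand apart. Where 1 library remained at 14 dpa, it was assumed to vary like the other groups.

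Between 3 and 7 dpa the largest falls were in tph1b, from 78.9 ± 15.5 to 1.57 ± 0.772 TPM (-4.98 ± 0.22), the calmodulin regulator pcp4a (-3.44 ± 0.15) and the basement membrane gene frem3 (-3.41 ± 0.40). The largest rises were in ccl27b (4.53 ± 0.30), the olfactomedin family gene olfml2ba (3.53 ± 0.23) and the cartilage matrix gene ucmaa (3.34 ± 0.30). In this step 1883 genes passed, 1030 higher and 853 lower. Between 7 and 10 dpa 2 genes passed in limma, the defensin gene defbl1 (1.74 ± 0.23) and the cartilage collagen gene col9a2 (1.14 ± 0.15), each with adjusted p = 0.0310, and 809 had an unadjusted p under 0.05. The gene col9a2 lies outside the naming rule and was chosen after its values were seen. Leaving out 1 library gave 0 genes without 7 dpa replicate 1 or 10 dpa replicates 2 or 3 (625, 397 and 579 at an unadjusted p under 0.05), 1 without 7 dpa replicate 2 or 3 and 5 without 10 dpa replicate 1. The col9a2 call was lost with each of these 6 libraries left out. It had adjusted p = 0.127, 0.0956 and 0.227 without 7 dpa replicates 1, 2 and 3 and 0.0504, 0.290 and 0.125 without 10 dpa replicates 1, 2 and 3. The 1 gene without 7 dpa replicate 2 was LOC100535095, and without replicate 3 it was defbl1. The 5 without 10 dpa replicate 1 were defbl1, mpeg1.3, prickle1b, vcana and LOC100006889. These too were named after their values were seen. The defbl1 call was lost without 7 dpa replicate 1 (adjusted p = 0.127) or 2 (0.106) and without 10 dpa replicate 2 (0.290) or 3 (0.157). Of these 6 libraries, 7 dpa replicate 2 and 10 dpa replicates 2 and 3 stand apart. Without the 4 libraries, with 1 library left at 10 dpa, 0 genes passed in limma and 431 had an unadjusted p under 0.05.

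Between 10 and 14 dpa irg1l rose from 12.7 ± 20.1 to 427 ± 149 TPM (6.28 ± 1.26, adjusted p = 0.0109), scpp8 by 5.27 ± 0.51 and agr2 by 3.34 ± 0.31. With 14 dpa replicate 1 or 2 left out, irg1l had adjusted p = 0.0792 and 0.0937. The fibril gene and3 (-2.63 ± 0.58), enam (-2.51 ± 0.29) and the cartilage collagen gene col9a1a (-2.14 ± 0.30) fell. The and3 call was lost without 10 dpa replicate 2 or 3 (adjusted p = 0.0603 and 0.0694), without 14 dpa replicate 1 or 2 (0.195 and 0.0605) and, with 1 library left at 10 dpa, without the 4 libraries (0.101). Of 989 genes past the threshold, 579 were higher and 410 lower, against 351 and 552 with median-of-ratios scaling. The count was 456 and 384 without 10 dpa replicate 2 or 3, 128 and 205 without 14 dpa replicate 1 or 2, and 472 without the 4 libraries. Where 1 library remained at 10 or 14 dpa, it was assumed to vary like the other groups.

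From 3 to 14 dpa the largest rises were in irg1l (7.41 ± 1.26), ccl27b (4.93 ± 0.34) and scpp8 (4.90 ± 0.51), and the largest falls in frem3 (-5.52 ± 0.44), vcana (-5.33 ± 0.32) and scpp7 (-5.29 ± 0.32). Interferon genes were higher at 14 dpa in 20 of 21 (adjusted p = 1.21e-11, and adjusted p = 0.102 with an estimated correlation), 21 adjusted over the list alone. Ionocyte markers were higher in 5 of 8 (adjusted p = 0.0129, and adjusted p = 0.107 with an estimated correlation), 6 adjusted over the list alone, but in 2, 3 and 2 without 3 dpa replicate 1 or 2 or 14 dpa replicate 1. Fgf ligands were lower in 6 and higher in 1 of 12 (adjusted p = 0.00652, and adjusted p = 0.0956 with an estimated correlation), 7 and 2 adjusted over the list alone. In all 3842 genes passed, 2228 higher and 1614 lower, and 2535 passed without 14 dpa replicate 2.

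Over the 11 libraries from 3 to 14 dpa, Fgf ligand transcripts declined. Of 12 ligands 7 fell with time (adjusted p = 0.00396, and adjusted p = 0.0590 with an estimated correlation, and 2.43e-07 in fry), fgf20a by -0.34 ± 0.04 on the log2 scale per day (adjusted p = 0.000138), fgf3 by -0.18 ± 0.02, fgf4 by -0.16 ± 0.02 and fgf2 by -0.13 ± 0.03. Mean fgf20a was 27.3 ± 5.83, 4.94 ± 1.48, 2.75 ± 1.14 and 1.51 ± 0.343 TPM at 3, 7, 10 and 14 dpa (SD, n = 3, 3, 3 and 2). Of 20 Erk feedback genes 4 fell and 2 rose, and the list passed neither in camera (adjusted p = 0.409, with a median and mean above 0 and a test pointing down) nor in fry (0.146, also down). Those that fell were myca (-0.18 ± 0.02), etv5b (-0.14 ± 0.02, adjusted p = 5.46e-05), etv5a (-0.09 ± 0.02) and etv4 (-0.08 ± 0.02). Those that rose were dusp7 (0.07 ± 0.02) and egr2b (0.09 ± 0.02), an immediate early factor. The egr2b call was lost without 14 dpa replicate 2 (adjusted p = 0.0511), and dusp7 had adjusted p = 0.0533 after quantile normalization. Among 7 receptor genes fgfrl1a fell (-0.13 ± 0.02) and the list did not pass (adjusted p = 0.228). In the fin length list 4 of 13 fell, rcan2 (-0.17), sema3d (-0.15), hapln1a (-0.15) and scube3 (-0.13), and 2 rose, the calcineurin subunits ppp3ca (0.08) and ppp3cb (0.07) (adjusted p = 0.435). The slope of kcnk5b was 0.05 ± 0.02 (adjusted p = 0.0620).

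Blastema and skeletal transcripts also declined with time. Blastema genes fell in 18 of 28 (adjusted p = 1.48e-10, and adjusted p = 0.00199 with an estimated correlation), tnc by -0.34 ± 0.02 and msx2b by -0.31 ± 0.05 per day. Matrix genes fell in 14 of 22 (adjusted p = 8.38e-09, and adjusted p = 0.00826 with an estimated correlation) and actinotrichia genes in 9 of 11 (adjusted p = 4.44e-09, and adjusted p = 0.0776 with an estimated correlation). Osteoblast genes fell in 12 of 21 (adjusted p = 3.13e-06, and adjusted p = 0.214 with an estimated correlation), with col1a1a at -0.28 ± 0.02 and the periostin gene postnb at -0.28 ± 0.02. Fibroblast markers fell in 8 of 11 (adjusted p = 0.000103, and adjusted p = 0.0590 with an estimated correlation). The 8 steepest falls were frem3 (-0.53), vcana (-0.51), scpp7 (-0.50), tph1b (-0.48), pcp4a (-0.46), the basement membrane gene frem2a (-0.44), and2 (-0.43) and the extracellular chaperone clu (-0.38).

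Wnt genes fell in 13 of 25 and rose in 1 (adjusted p = 0.000103, and adjusted p = 0.0590 with an estimated correlation), led by sfrp2 (-0.33 ± 0.04) and the nuclear effector lef1 (-0.25 ± 0.02), and 8 fell without 3 dpa replicate 2. Bmp and Tgfb genes fell in 15 of 27 (adjusted p = 7.32e-06, and adjusted p = 0.0776 with an estimated correlation), Hedgehog genes in 7 of 11 (adjusted p = 0.000148, and adjusted p = 0.0776 with an estimated correlation), with shha at -0.20 ± 0.04, and positional genes in 14 of 25 (adjusted p = 1.17e-06, and adjusted p = 0.0776 with an estimated correlation). Retinoic acid genes fell in 8 of 18 and rose in 2 (adjusted p = 0.0118, and adjusted p = 0.156 with an estimated correlation), with aldh1a2 at -0.28 ± 0.02 and rbp4 at 0.25 ± 0.05. Endothelium markers fell in 9 of 18 and rose in 2 (adjusted p = 0.00908, and adjusted p = 0.176 with an estimated correlation), with 5 fallen without 14 dpa replicate 2. Cell cycle genes were called lower with 2 of 39 fallen (adjusted p = 0.00462, and adjusted p = 0.606 with an estimated correlation, and 0.155 in fry). In limma 0 fell without 3 dpa replicate 2 or 3 or 10 dpa replicate 1 (2, 1 and 4 at an unadjusted p under 0.05), 1 without 3 dpa replicate 1 or 10 dpa replicate 2 and 5 without 14 dpa replicate 1.

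Interferon genes rose with time in 21 of 21 cases (adjusted p = 4.27e-12, and adjusted p = 0.0590 with an estimated correlation), the antiviral gene rsad2 by 0.32 ± 0.05 and mxb by 0.27 ± 0.04 per day. This list had a median loading at percentile 99.6 on the first component within times, and without the 4 libraries that stand apart 21 still rose. Pigment cell markers rose in 11 of 17 (adjusted p = 0.000154, and adjusted p = 0.340 with an estimated correlation), such as tyrp1b of melanin synthesis (0.30 ± 0.08), and 5, 7 and 6 rose without 3 dpa replicate 1, 2 or 3. Superficial epidermis markers rose in 8 of 15 and fell in 1 (adjusted p = 0.000489, and adjusted p = 0.149 with an estimated correlation), including agr2 (0.35 ± 0.06) and the claudin cldne (0.21 ± 0.02), and 4 and 5 rose without 3 dpa replicate 1 or 2. Macrophage markers rose in 8 of 16 and fell in 1 (adjusted p = 0.00189, and adjusted p = 0.298 with an estimated correlation). Neutrophil markers rose in 7 of 11 and fell in 1 (adjusted p = 0.00619, and adjusted p = 0.0776 with an estimated correlation), with the myeloperoxidase gene mpx at 0.26 ± 0.03. Lymphocyte markers rose in 6 of 9 (adjusted p = 0.00491, and adjusted p = 0.244 with an estimated correlation), lck by 0.22 ± 0.04. In the Yap/Taz list 5 of 12 rose (adjusted p = 0.0330, and adjusted p = 0.415 with an estimated correlation), among them ccn2b (0.19 ± 0.04). Without 3 dpa replicate 1, 2 or 3 or 14 dpa replicate 1, 3 rose, and the call was lost without 3 dpa replicate 3 (adjusted p = 0.182).

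The 8 steepest rises were in irg1l (0.60 ± 0.15), ccl27b (0.48 ± 0.10), hspa12a.3 (0.43), scpp8 (0.39 ± 0.12), mpeg1.3 (0.39), prg4a (0.38), sqlea, a sterol synthesis enzyme (0.38), and the sulfotransferase sult5a1 (0.38). The irg1l call was lost without 14 dpa replicate 2 (0.47, adjusted p = 0.0574), and the scpp8 call without 14 dpa replicate 1 (0.25, adjusted p = 0.123) or replicate 2 (0.29, adjusted p = 0.123). In all 3473 genes had a slope past the threshold, 1958 rising and 1515 falling. Adjusted over the list alone, counts of rising and falling genes differed for Wnt with 1 and 15, Bmp and Tgfb with 0 and 17, retinoic acid with 2 and 9, osteoblast with 1 and 13, cell cycle with 0 and 0, matrix with 0 and 15, fin length with 4 and 4, positional with 1 and 16, basal epidermis with 4 and 3, superficial epidermis with 11 and 1, fibroblast with 1 and 8, lymphocyte with 7 and 0, muscle with 1 and 2, erythrocyte with 2 and 2 and lateral line with 3 and 1.

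**Figure D3:**
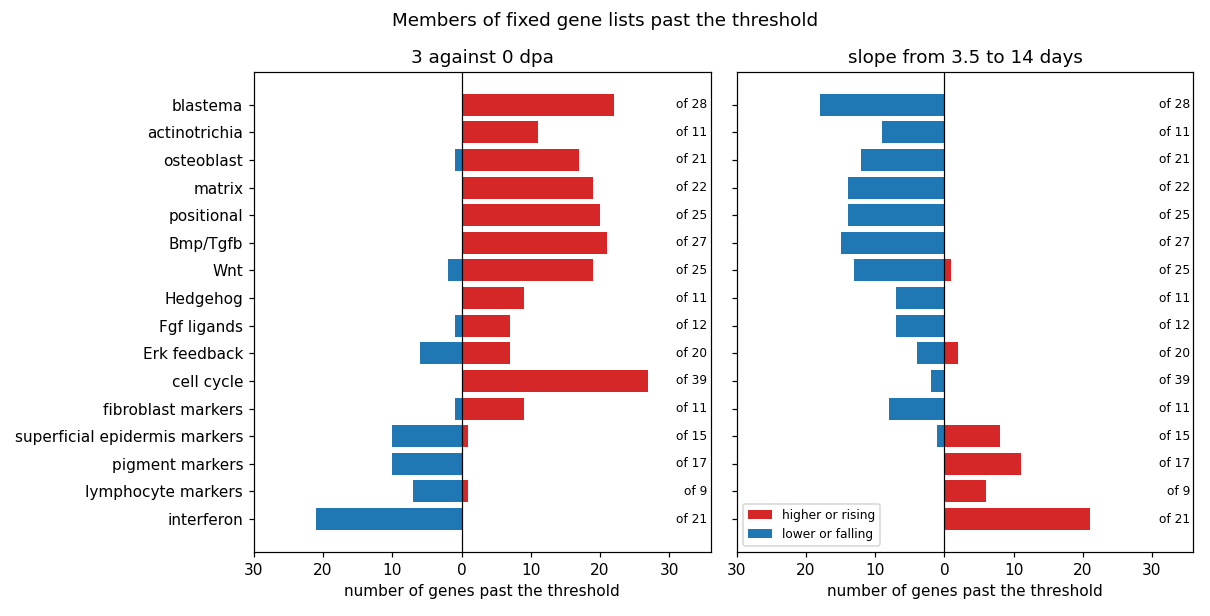
Number of genes past the threshold in 16 of the 32 fixed lists, higher or rising to the right and lower or falling to the left, for 3 against 0 dpa (left) and for the slope from 3.5 to 14 days (right). The text at the right edge gives the genes tested, for example 22 of 28 blastema genes higher at 3 dpa and 18 falling later.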

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

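The tests of handling, time of day, cell types, scaling and the first component within times were chosen after the results they bear on were seen. The splits of the libraries were planned before.

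Changes against 0 dpa of 8 named genes went in opposite directions at 3 and 14 dpa, both past the threshold. Passing in 14 against 3 dpa was also required of them, so its limma p-values below describe the difference and are no independent test. Among pigment genes the log2 difference from 3 to 14 dpa was 2.15 for dct (adjusted p = 3.92e-05), 2.25 for pmela (3.28e-05) and 2.92 for tyrp1b (1.42e-06). Among interferon genes it was 3.09 for mxb (2.59e-06) and 3.68 for rsad2 (1.50e-05). The mucus cell gene agr2 differed by 4.12 (1.42e-06) and the neutrophil gene npsn by 2.05 (1.92e-05), and clu went the other way, -3.97 (2.44e-06). With median-of-ratios scaling 4 of the changes from 0 to 14 dpa were smaller, with a like spread, and lost their call: they were, as deposited and scaled, 1.18 ± 0.25 and 0.90 ± 0.27 for dct (adjusted p = 0.0850), 1.23 ± 0.25 and 0.91 ± 0.28 for mxb (0.0913), 1.14 ± 0.26 and 0.83 ± 0.28 for pmela (0.121), and 1.09 ± 0.41 when scaled for rsad2 (0.167). After quantile normalization those of dct (0.77, adjusted p = 0.181), npsn (0.76, 0.0515), pmela (0.91, 0.0679) and rsad2 (1.18, 0.150) were lost. Without 14 dpa replicate 1 the call was also lost for clu (0.0748), and without replicate 1 or 2 for npsn (0.0790 and 0.0718), dct (0.105 and 0.0923), pmela (0.0609 and 0.143), mxb (0.0994 and 0.0803) and rsad2 (0.264 and 0.107). Leaving out 1 of the 0 dpa libraries did so for rsad2 without replicate 1 or 2 (0.0564 and 0.129) and, without replicate 3, for dct (0.0508) and pmela (0.0547).

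The 4 libraries that stand apart came from 3 different times, and the first component of the spread within times held 59.6% of that spread. With fosb and atf3 left out, 21 stress and immediate early genes had a median loading at percentile 100 of random lists. Random lists hold genes that need not vary together, and the cell cycle list also lay at 100 and Notch at 0.07. The percentile thus does not single out handling before lysis. Handling may contribute, as a hypothesis, and no label records it. Collection at another time of day cannot be told apart, since with npas2, per2, cry5 and nr1d1 left out, which had been read off these libraries, the mean absolute loading of 27 clock genes lay at percentile 89.7, and at 93.0 with nr1d1 kept. With all 31 clock genes, those read off included, it lay at percentile 99.98. Another mix of cell types cannot be told apart either, since 4 of 13 marker lists lay outside 95% of random lists, macrophages and lymphocytes above, superficial epidermis and erythrocytes below. No further biological explanation was tested, because no group of the design separates these libraries.

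Interferon and sterol synthesis genes were higher at 14 than at 3 dpa, with a median log2 difference of 2.05 over 44 genes. A shift along the first component within times would by itself move the 2 lists apart, since their loadings lie at percentiles 99.6 and 0. But interferon genes rose by a median of 1.82 and sterol genes by 2.11. Such a shift is thus argued against as the cause of both, and a part in either stays open. Scaling is argued against, since the median was 1.99 with median-of-ratios scaling. Between these times that scaling moved the median gene only from 0.05 to 0.003, too little to remove such a rise whatever its cause. A larger share of superficial epidermis at 14 dpa may account for it and cannot be told apart. These genes rose by 0.77 more than its markers (permutation test, two-sided, p = 0.0526). Genes, not animals, were permuted, and the sterol genes were listed after some of their values were seen, so the test decides nothing. Time after amputation itself stays open and untested.

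Fibroblast, blastema, matrix and osteoblast lists were called higher at 3 than at 0 dpa, and lymphocyte, macrophage, interferon, pigment and superficial epidermis lists lower, while basal epidermis and neutrophils did not pass and 1 of the 18 called lists, blastema, passed with an estimated correlation. If lymphocytes lie outside the epidermis, a lower share of epidermis alone would raise their markers and those of fibroblasts alike. The median of 11 fibroblast markers was 2.40 and that of 9 lymphocyte markers -1.58. The difference was 3.98 (exact permutation test over 167960 splits of the markers, two-sided, p = 0.00150), where genes, not animals, were permuted. Both lists had already been called in opposite directions, so this p-value is no independent support. Where the lymphocytes lay was not measured, and any within the epidermis would fall with it. A lower share of epidermis therefore stays open. Scaling is argued against for the lists called higher, since with median-of-ratios scaling 61 of 64 called members kept their call, and it moves the others further down, so it is no test of the lists called lower. Whether more fibroblasts, or more transcript per cell, may underlie the rise stays open, as does time after amputation.

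The libraries were also split in other ways. For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. At 3 against 0 dpa the real split gave 6159 genes and was the 1 split of 10 with as many, with at most 0 in another. At 7 against 0 dpa these were 3442, 1 of 10 and 0, and at 7 against 3 dpa 1883, 1 of 10 and 0. At 10 against 0 dpa the real count was 1885, 1 of 10 splits gave as many, and the highest other gave 1455. That split set 0 dpa replicate 1 and 10 dpa replicates 2 and 3, which stand apart, against the remaining 3. At 10 against 7 dpa the real count was 2, and 2 of 10 splits gave as many. The other, with 2896 genes, set 7 dpa replicate 2 and 10 dpa replicates 2 and 3 against the remaining 3, which points to the structure of these libraries. For change at any time 1 of 100 orders of the labels, the real order included, gave as many as the real 5364. The highest other gave 2803. For the slope 1 of 100 gave as many as 3473, with 2501 as the highest other. A random order of the labels is thus argued against for both, but 100 orders cannot exclude it. Anything shared by the libraries of a time cannot be told apart from time here.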

How the results depend on the processing

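Leaving out the 4 libraries that stand apart, and the covariate for the first component within times, were chosen after seeing the data. Leaving out 1 library at a time gave these counts of genes past the threshold: 5120 to 6208 for 3 against 0 dpa, 2494 to 3816 for 7 against 0, 1196 to 2622 for 10 against 0, 180 to 1984 for 14 against 0, 1314 to 1576 for 7 against 3, 0 to 5 for 10 against 7, 128 to 1273 for 14 against 10, 2535 to 3451 for 14 against 3, 4429 to 5943 for any time and 2651 to 3603 for the slope. The 2 genes of 10 against 7 dpa became 0 with a pseudocount of 0.1, 1 with 5, 4 without a filter (more genes tested) and 0 with a mean of at least 5 TPM (fewer genes tested), only both groups' libraries, or without the 4 libraries, where limma gave 768, 610, 538 and 431 genes at an unadjusted p under 0.05. For 14 against 0 dpa the 1265 genes became 525 with median-of-ratios scaling, 409 with quantile normalization, 252 with only both groups' libraries (fewer samples) and 3448 without the 4 libraries. For 14 against 10 dpa the 989 became 404 with only both groups' libraries and 472 without the 4 libraries. Without them 1 library remains at 10 dpa and 2 each at 0 and 7 dpa, and the lone one is assumed to vary like the others (fewer samples). Library weights, which ran from 0.242 for 0 dpa replicate 1 to 5.85 for 10 dpa replicate 2, gave 5349 genes for 7 against 0, 6433 for 10 against 0, 4985 for 14 against 0, 3091 for 7 against 3, 3211 for 10 against 7, 5027 for 14 against 10 and 9951 for any time. The covariate gave 5599, 3980, 3968, 4045, 340, 3409 and 8373 for the same 7, and it takes up spread estimated from the same values. Where no construction is named, the cause was not tested. For 10 against 7 dpa without a filter, the larger number of genes tested is not shown to be the cause either. A gene newly called there, ckma, had passed the filter as well. Of 192 list tests 102 passed, 14 did with an estimated correlation, and 99 to 108 did with 1 library left out, repeats that were also added after seeing the data. In fry 26, 25, 25, 20, 23 and 22 of 32 passed for 3, 7, 10 and 14 against 0 dpa, 14 against 3 and the slope. With the replicate number as a block the counts were 5916, 3174, 1648, 868, 1627, 0, 817, 3489, 4903 and 3161, in the order of the ranges. Of the 20 lists called for the slope 19 kept their call with the block, and all lists called in the other comparisons did. The numbers do not pair the libraries: 10 of 26 pairs with the same number had deviations correlated over 0.1 (-0.772 to 0.571), and 2 of 14 libraries correlated best with their own number. Other counts stayed within 1.5 times under the remaining settings. Of 404 values of named genes past the threshold, 115 lost the call under at least 1 setting fixed in advance, and 0 turned direction under any setting run. Unknown depth limits what can be said of low genes.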

Other observations

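Sterol synthesis genes, listed after some of their values were seen, were low at 3 dpa. Of 23 tested, 15 fell against 0 dpa with a median log2 change of -1.80, and 19 were higher at 14 than at 3 dpa, with a median of 2.11. Mean hmgcs1, an early enzyme of the pathway, was 189.5 ± 76.0 TPM at 0 dpa, 35.2 ± 4.95 at 3, 87.7 ± 44.0 at 7, 75.3 ± 24.0 at 10 (SD, n = 3 each) and 259.7 ± 54.0 at 14 dpa (n = 2). The rate-limiting enzyme gene hmgcra was at 4.19, 17.1 and 9.92 TPM in the 3 dpa libraries and at 142, 278 and 269 at 0 dpa. These genes also vary within times. Their median loading lay at percentile 0 of random lists on the first component within times. The lipoprotein receptor gene ldlra was at 27.3, 14.8, 17.8 and 15.7 TPM in the 4 libraries that stand apart (0 dpa replicate 1, 7 dpa replicate 2 and 10 dpa replicates 2 and 3), and at 14.9 to 162 in the others. From 10 to 14 dpa 7 of 23 rose, and 2 did without those libraries, where 1 library remained at 10 dpa.

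Clock genes, also chosen after their values were seen, were read in single libraries. The clock activator npas2 was at 1.62, 2.14, 2.25 and 2.03 TPM in those 4 libraries, in the same order, and at 6.05 to 23.2 TPM in the others. The light-induced cry5 was at 13.4, 6.16, 26.4 and 15.9 TPM, and at 19.1 to 109 in the others.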
